A study of Mus musculus with 6 samples.

How the data were processed

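RNA-seq was performed on 4T1 cells, a mouse mammary carcinoma line, in 6 samples: 3 carried the empty pLVX vector (control) and 3 carried the same vector with LINC01133, a human long noncoding RNA. Total RNA was made into Illumina TruSeq libraries, per the labels' protocols. The authors deposited a single table of raw whole-number counts per gene for the 6 samples, with a gene length and a UCSC transcript identifier paired with each symbol, per the file headers. The mm10 build and bcl2fastq are named in the submitters' processing notes. The aligner, the counting tool, the annotation version and whether counting used the strand are not given in the sources used here. Reads of a gene and of an overlapping or antisense partner (Xist and Tsix, for example) therefore cannot be told apart, and members of families with near-identical copies (histones, ribosomal proteins, the Oas and Ifit genes) are uncertain where the authors' counting could split them. The number of columns that belong to no sample in the labels was 0.

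Samples were grouped by their titles. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within each group the replicates were compared by a chi-square statistic over rows with at least 20 summed counts, leaving out Rn45s. It lay between 1.61 and 2.32 per degree of freedom over the 6 pairs, above sampling noise, so each sample was counted as 1 replicate.

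The table held 31854 rows, of which 22697 had at least 1 count. Where rows shared a symbol, the row with the highest mean kept it and the others were named by symbol and identifier, a choice made after the table was seen. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr on the groups and robust dispersions, over 14116 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05; a gene past it is called. The common biological coefficient of variation was 0.0237. Levels are CPM on TMM-scaled library sizes, as mean ± SD over the 3 libraries of a group, and log2 fold changes are LINC01133 against control. Where a group had no read, the fold is a lower bound against a floor of 3 counts over the group; where it had 1 to 3 counts, the ratio has an exact 95% interval. Floors and intervals cover counting error only. On counts simulated from the means and library sizes of this comparison, 13732 genes were tested. Among better-covered genes, 50 per fold were changed in random directions, with a single dispersion for all genes. The test recovered 70% of genes changed 1.25-fold, 90% at 1.5-fold and 100% at 2-fold and 4-fold, with 15 false calls. Far fewer genes were changed than were called in the data, so these rates do not carry over to the real comparison.

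Before the data were examined, 36 gene lists were written. They were tested with camera (limma 3.58.1) on voom values at a preset inter-gene correlation of 0.01, for lists with at least 3 tested members, with adjustment over the lists; 34 could be tested. The lists of mitochondrial mRNAs and Y-linked genes are not analysed here. Of the 803 symbols written, 753 were found among the rows. The called members of a list were also counted with p-values adjusted over the list alone. Shares of counts were compared by an exact two-sided permutation test, which with 3 against 3 samples cannot go below 0.1.

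The genes named were also set by a rule written before the data were examined: the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM and groups that did not overlap, leaving out predicted genes; up to 4 members of each called list in its direction and up to 2 in the other, and up to 2 called members of each other list, by smallest p; and, whatever their values, Klf4, Sox2, Pou5f1, Nanog, Myc, Foxp2, Cdh1, Epcam, Vim, Mki67 and Cd274. It gave 168 genes, and the text names part of them. Genes named outside it are said to be so. Gene positions are from GENCODE M21, an annotation of the same mouse assembly, matched by symbol for 12767 tested genes.

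Alternatives were RLE, library size alone and upper-quartile scaling; no count filter, or at least 1 CPM in at least 3 libraries; the replicate number as a block; each sample left out in turn; dispersions without the robust option; DESeq2 1.42.0 and limma voom; an adjusted p under 0.01 and an added 2-fold limit; and for lists an estimated correlation and fry. Leaving out the Rn45s row and following the 2-fold counts through the other alternatives were added after seeing the data. The LINC01133 transcript itself was not analysed here, so its level is no check of the labels. Figures were drawn with matplotlib 3.10.9.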

Results

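The transcriptomes of 4T1 mouse mammary carcinoma cells carrying a LINC01133 expression vector were compared with those of cells carrying the empty vector, to find which mouse genes differ between them. The labels do not say whether both groups came from the same parental cells, and no parental sample was analysed here. A difference between the groups is therefore not by itself an effect of LINC01133, and "with LINC01133", "rose" and "fell" below only compare the groups. Each group had 3 libraries. Total counts were 27035127, 25686811 and 25521469 in the controls and 26719396, 33877549 and 30340815 with LINC01133, so that 3 counts in a library correspond to 0.0827 to 0.128 CPM. Rn45s, the 45S ribosomal RNA precursor, took 26.75% ± 1.245 of control counts and 21.91% ± 0.9778 of LINC01133 counts (SD, n = 3; exact two-sided permutation p = 0.1, the smallest this design allows). Between 12404 and 12464 rows had at least 10 counts in a control library, and between 14078 and 14491 in a LINC01133 library.

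With LINC01133, epithelial and luminal genes, interferon response genes and immediate early genes were higher, and genes of lipid synthesis, mitosis, the ribosome and the antioxidant NRF2 response were lower, by a test of gene lists at a preset correlation. With an estimated correlation none of these lists was called (adjusted p = 0.076 to 0.20). Krt18, a keratin of simple epithelia, went from 2.06 ± 0.213 to 158.2 ± 4.45 CPM, while N-cadherin (Cdh2) went from 104.4 ± 1.75 CPM to 2 counts over 3 libraries (SD, n = 3). These 2 genes do not stand for their kinds. The mesenchymal and EMT list that holds Cdh2 was not called, with 15 of 25 members lower and 9 higher. Its member Vim rose, and the epithelial genes Cdh1 and Epcam stayed low in both groups. The 2 groups differed in most expressed genes: 6280 of 14116 tested genes were higher and 5710 were lower, and 2126 were not called. At least a 2-fold difference was found in 2860 higher and 1959 lower genes, and at least an 8-fold difference in 1403 and 484. Part of these genes had low levels. Among the 12470 genes with at least 1 CPM in at least 3 libraries, 2070 were 2-fold higher and 1683 were 2-fold lower. The 3 values of one group lay wholly above or below those of the other in 12003 of the 14116 genes, 85%, against 10% by chance. Scaled by library size alone, the median log2 fold change of all genes moved by 0.24 and the split became 7847 higher and 4228 lower, 65% of calls higher against 52.4%. A total of 10 genes had at least 20 CPM with LINC01133 and no read in any control, and 9 had at least 20 CPM in the controls and no read with LINC01133. Under 1% of the other group's level were found 76 and 80 genes.

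**Figure D1:**
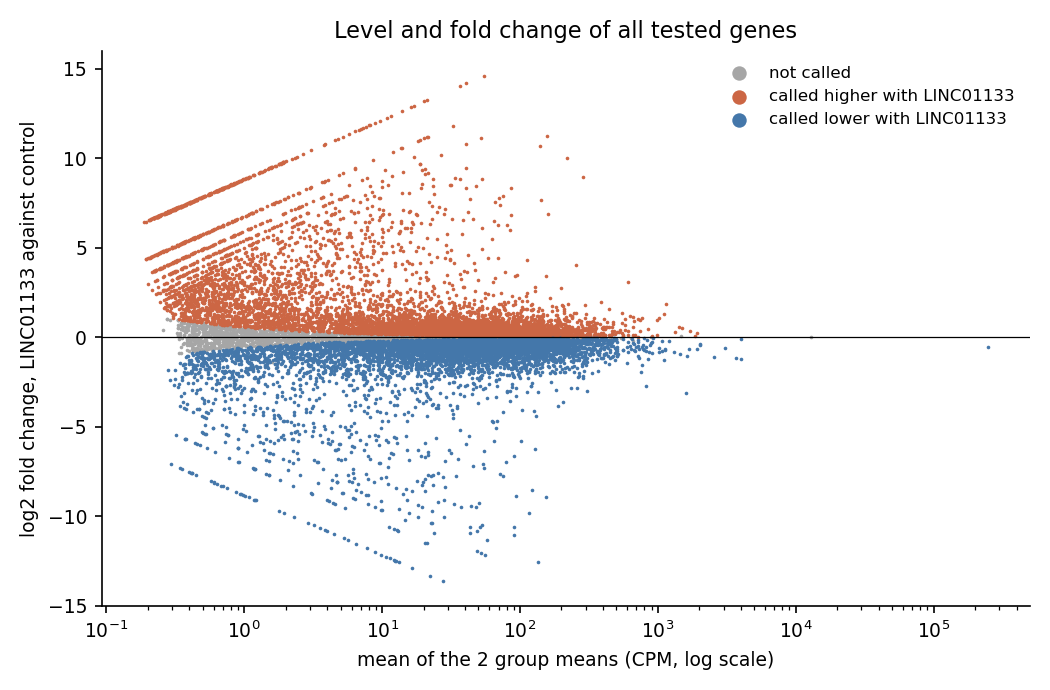
Each point is a tested gene, with the mean of both group means in CPM on a log axis and the log2 fold change of LINC01133 against control on the vertical axis; colours mark genes called higher, called lower and not called. The 6280 higher and 5710 lower genes spread over the whole range of levels, and the slanted edges are genes with no or few reads in one group.

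The 10 highest genes had no read in the controls. Gpnmb, a transmembrane glycoprotein (uc012elo.1, chromosome 6, 49036546 to 49070929 on mm10), stood at 108.9 ± 1.28 CPM with LINC01133, at least 2610-fold higher (adjusted p = 4.6e-114). Ano1, a calcium-activated chloride channel (uc009kqn.2, chromosome 7, 144588549 to 144751974), stood at 81.8 ± 1.51 CPM, at least 1958-fold higher. Ngfr, the low-affinity neurotrophin receptor (uc007lam.2, chromosome 11, 95568818 to 95587735), stood at 73.1 ± 2.45 CPM, at least 1755-fold higher. The others were Mgat3, Pdzrn3, the Notch ligand Dll1, Disp1, Arrdc4, the secreted Wnt antagonist Sfrp1 and the endothelial lipase gene Lipg, at 21.8 to 42.4 CPM and at least 521-fold to 1016-fold higher.

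Among the 10 lowest genes, Tmem47 (uc009tre.2, chromosome X, 81070698 to 81097872) fell from 55.0 ± 2.12 CPM to no read, at least 1813-fold lower (adjusted p = 1.6e-99). Tceal8, Clca3a1, Lrch2, Ptchd4, Tspan6, Prkd1 and AI414108 likewise had no read with LINC01133, from 21.4 to 44.8 CPM in the controls. Twist1, a transcription factor of mesenchymal development (uc007niw.1, chromosome 12, 33957671 to 33959829), was at 24.4 ± 1.73 CPM in the controls and had no read with LINC01133, at least 805-fold lower. Ly6e, a membrane-anchored surface protein, fell from 272.0 ± 15.5 CPM to 4 counts over 3 libraries (log2 fold change -12.56, SE 0.099, adjusted p = 2.8e-78). Of these 10 genes, 4 are on the X chromosome, against 0 of the 10 highest. Xist, the noncoding RNA that coats the inactive X chromosome (uc009tzo.1, chromosome X, 103460366 to 103483254), fell from 57.0 ± 1.60 to 0.173 ± 0.0451 CPM (adjusted p = 7e-101).

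**Figure D2:**
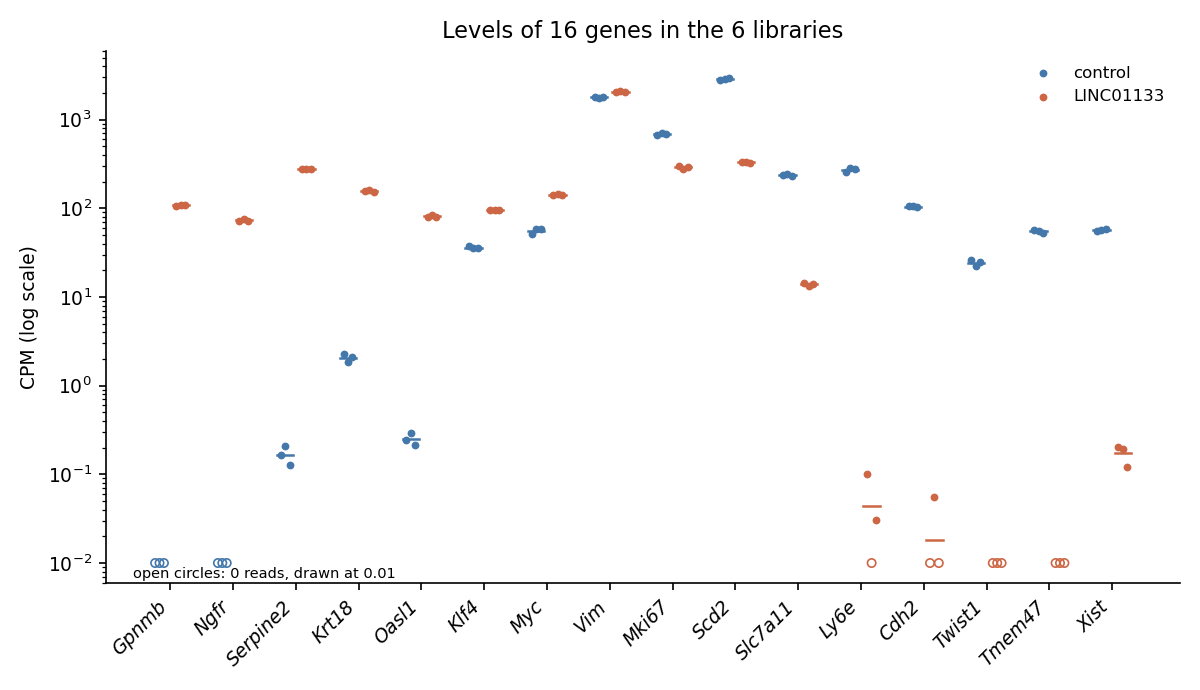
Levels in CPM, on a log axis, of 16 genes in the 3 control and 3 LINC01133 libraries; points are libraries, lines are group means, and open circles are libraries with 0 reads, drawn at 0.01. Replicates lie close together beside the differences between groups, and Vim moves least, from 1785 to 2078 CPM.

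Among genes examined whatever their values, Klf4, a zinc finger factor used in reprogramming to pluripotency, rose from 36.2 ± 0.913 to 96.1 ± 0.737 CPM (log2 fold change 1.41, SE 0.0398, adjusted p = 1.7e-67). Myc rose from 56.0 ± 3.55 to 143.3 ± 3.48 CPM (1.36, SE 0.0345, adjusted p = 1.3e-71). Sox2, Pou5f1, Nanog and Foxp2 stayed below the count filter, with at most 27 counts over the 3 libraries of a group. Mki67, a proliferation marker, fell from 689.5 ± 14.1 to 292.6 ± 10.9 CPM (log2 fold change -1.24). Vim, the mesenchymal intermediate filament, rose from 1785 ± 44.9 to 2078 ± 34.7 CPM (0.22). Cd274, which encodes PD-L1, rose from 2.03 ± 0.361 to 6.50 ± 0.280 CPM (1.68). The epithelial adhesion genes Cdh1 and Epcam were called higher at low levels, Cdh1 from 4 to 138 counts and Epcam from 0 to 78 counts, at least 18.9-fold. Both genes thus stayed low in both groups, and whether the cells are the line stated in the labels was not checked here.

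With camera at the preset correlation, 8 of 34 gene lists were called higher and 12 lower. With an estimated correlation none was called (camera, 0 higher and 0 lower; 5 higher and 7 lower at an unadjusted p under 0.05), and fry, which tests whether a list moves on balance without comparing it with other genes, called 17 higher and 15 lower. Counts of members below are over all genes tested, and the counts adjusted over the list alone were equal except where given. No list changed the sign of its median under the 3 other scalings, and for the lists called, medians that moved by over 1.5 times under a setting are given with the list.

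Epithelial junction and keratin genes rose, 15 of 18 tested members being higher and 2 lower, or 16 and 2 adjusted over the list alone (median log2 fold change 3.31; adjusted p = 0.0011, and adjusted p = 0.094 with an estimated correlation). Beside Krt18, the desmosomal gene Pkp3 rose from 3.31 ± 0.420 to 80.5 ± 1.75 CPM. Spint1, a protease inhibitor, went from 3 to 3705 counts, a ratio of 898 (95% interval 307 to 4357). Tjp1 and Krt7 fell (log2 fold changes -0.41 and -1.71). Mammary luminal genes also rose, with 10 of 12 higher and 2 lower (median 3.54, or 3.29 with genes at 0 reads set at their bound, adjusted p = 0.012, and adjusted p = 0.13 with an estimated correlation). Their median was 2.29, 2.19 and 2.00 without control 1, 2 and 3, 2.18 without LINC01133 replicate 2, and 2.19 with the CPM filter. They included Ehf (4.93) and the milk protein gene Csn3, which had no read in the controls and 11.6 ± 1.52 CPM with LINC01133, while the estrogen receptor gene Esr1 fell from 22.7 ± 0.693 to 1.61 ± 0.308 CPM.

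Mesenchymal and EMT genes were not called as a list (15 of 25 lower and 9 higher, with 10 and 6 at least 2-fold, adjusted p = 0.16). Cdh2 fell by a ratio of 5160 (95% interval 1428 to 42620), and the transcription factor gene Prrx1 from 66.6 ± 2.60 to 0.109 ± 0.113 CPM. Mmp3, a matrix protease also in this list, rose from 0.264 ± 0.205 to 23.2 ± 0.704 CPM. Mammary basal genes were not called (6 higher and 8 lower of 15, adjusted p = 0.96), with a median of -0.77 and a mean of 0.90, of opposite sign; the progenitor marker Lgr6 was higher among them (8.08). Of the markers of other cell types, 1 list of 4 was called. Endothelial markers were higher in 6 of 6 tested members (median 4.68, adjusted p = 0.048, and adjusted p = 0.22 with an estimated correlation), and the highest of the 4 named, Egfl7, reached 9.65 ± 0.151 CPM. That call was lost without control 1, control 2 or control 3 (adjusted p = 0.051, 0.06 and 0.053) and with 5 other settings (range 0.032 to 0.11 over 14 settings), and the median was 1.72 without a count filter. Fibroblast markers went both ways, with 6 of 10 lower, Pdgfrb falling from 106.7 ± 2.47 to 0.775 ± 0.251 CPM, and 4 higher (adjusted p = 0.29). Leukocyte markers (6 higher and 2 lower of 9, adjusted p = 0.23, Cd68, 2.20, Itgam, 2.41) and adipocyte markers (2 higher and 1 lower of 4, adjusted p = 0.89) were not called.

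Interferon response genes rose in 30 of 37 tested members and fell in 6 (median 2.52, adjusted p = 4.6e-05, and adjusted p = 0.076 with an estimated correlation). Oasl1, an OAS-like antiviral gene, rose from 0.2503 ± 0.0392 to 81.6 ± 1.86 CPM, Ifit1 from 2.03 ± 0.398 to 35.5 ± 0.984 CPM and the chemokine gene Cxcl10 from 0.877 ± 0.0769 to 26.2 ± 0.651 CPM. Ifit2 and Oas1a fell (-1.51 and -1.85). Immediate early genes rose in 22 of 24 members and fell in 1 (median 1.14, adjusted p = 1.3e-06, and adjusted p = 0.20 with an estimated correlation), with Fos at 4.21, Fosb at 4.77 and Egr1 at 3.63 on the log2 scale; Ier2 was lower by TMM (-0.14) and higher by library size alone (0.10). Antigen presentation genes (11 higher and 8 lower of 19, adjusted p = 0.29, H2-D1, 1.27), NF-kB targets (10 higher and 6 lower of 17, adjusted p = 0.23, Tnfaip3, 3.51) and cytokines (13 higher and 9 lower of 24, adjusted p = 0.61) were not called. At least a 2-fold difference was found in 12 higher and 7 lower cytokines (median of the list 1.02). The 2 called cytokines with the smallest p both fell, Cxcl12 from 180.6 ± 2.38 to 0.114 ± 0.0548 CPM and Csf1 from 414.5 ± 14.4 to 57.3 ± 1.02 CPM.

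Matrix proteases and their inhibitors rose in 17 of 23 members and fell in 4 (median 0.95, adjusted p = 0.012, and adjusted p = 0.13 with an estimated correlation, and adjusted p = 0.056 by library size alone, range 0.0066 to 0.056). Serpine2, a protease inhibitor, rose from 0.167 ± 0.0402 to 278.9 ± 1.24 CPM, and the urokinase gene Plau from 0.167 ± 0.0402 to 62.7 ± 1.03 CPM, while Adamts5 fell from 918 to 2 counts, a ratio of 631 (95% interval 174 to 5219). Matrix and collagen genes were not called (15 higher and 9 lower of 26, adjusted p = 0.23); Lama5 was higher (1.11) and Col6a2 lower (-3.94). Notch pathway genes rose in 10 of 14 members and fell in 3 (median 1.04, or 1.59 without a count filter, adjusted p = 0.048, and adjusted p = 0.19 with an estimated correlation). Their call was lost under 6 of 14 settings, among them without LINC01133 replicate 1 (adjusted p = 0.051; range 0.012 to 0.12). Notch1 and Hes1 were higher (1.87 and 1.61), and Notch2 and Nrarp lower (-1.37 and -2.18). Wnt targets (8 higher and 3 lower of 15, adjusted p = 0.13), TGF-beta targets (11 higher and 7 lower of 20, adjusted p = 0.19; median 0.20, mean -0.20, with a median of 0.45 by library size alone and 0.08 without a count filter) and stemness genes (11 higher and 5 lower of 16, adjusted p = 0.054, and adjusted p = 0.048 without control replicate 3, range 0.048 to 0.1) were not called. Notum, a secreted Wnt inhibitor, went from 1 to 4230 counts, a ratio of 3076 (95% interval 551.8 to 121500), while the Wnt target Ccnd1 fell (-1.02). The stemness gene Sox9 rose from 15.7 ± 1.54 to 167.9 ± 2.76 CPM.

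YAP/TEAD targets fell in 12 of 17 members and rose in 5 (median -0.59, or -0.34 by library size alone, adjusted p = 0.029, and adjusted p = 0.19 with an estimated correlation). Fstl1 fell from 107.5 ± 1.74 to 1.32 ± 0.407 CPM, while Ctgf, a target often used as a readout, rose from 27.7 ± 0.673 to 87.6 ± 3.71 CPM. ER chaperone genes rose in 15 of 18 members and fell in 2 (median 0.59, adjusted p = 0.0011, and adjusted p = 0.14 with an estimated correlation), with Hspa5, the chaperone BiP, going from 635.5 ± 9.19 to 1568 ± 10.5 CPM; Calr was lower by TMM (-0.21) and higher, not called, by library size alone (0.04). Heat shock genes were not called (6 higher and 4 lower of 12, adjusted p = 0.51).

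Lipid synthesis genes fell. Of the cholesterol synthesis genes, 22 of 25 were lower and 3 higher (median -1.13, adjusted p = 1.3e-06, and adjusted p = 0.076 with an estimated correlation). Of the fatty acid genes, 14 of 17 were lower and 2 higher (median -1.02, adjusted p = 0.00032, and adjusted p = 0.091 with an estimated correlation). The desaturase gene Scd2 fell from 2888 ± 42.9 to 330.3 ± 1.43 CPM, and Fads1 from 187.5 ± 1.84 to 0.394 ± 0.0557 CPM. NRF2 targets fell in 17 of 19 members and rose in 0 (median -1.08, adjusted p = 1.2e-06, and adjusted p = 0.076 with an estimated correlation), and ATF4 targets in 17 of 23, with 6 higher (median -1.23, adjusted p = 0.00024, and adjusted p = 0.13 with an estimated correlation). By library size alone, the NRF2 targets Osgin1 and Gstm1, not called by TMM, were called higher (0.34 and 0.26), and Osgin1 also by upper quartile (0.20). Slc7a11, the cystine transporter in both lists, fell from 237.9 ± 5.71 to 13.9 ± 0.565 CPM, while Atf3 rose from 0.223 ± 0.0490 to 43.5 ± 1.31 CPM.

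Genes of the cell cycle, translation and respiration were lower. G2/M genes fell in 26 of 27 members and rose in 1 (median -0.74, or -0.49 by library size alone, adjusted p = 2.9e-08, and adjusted p = 0.085 with an estimated correlation); the mitotic kinesin Kif11 fell from 390.3 ± 9.17 to 103.2 ± 1.87 CPM, and Aurka was higher (0.32). G1/S genes fell in 18 of 27 and rose in 7 (median -0.36, or -0.11 by library size alone, adjusted p = 0.0065, and adjusted p = 0.19 with an estimated correlation), Pcna being higher (0.40) and Gins2 lower (-1.94). Replication-dependent histones fell in 14 of 19 and rose in 2 (median -0.53, or -0.29 by library size alone, adjusted p = 0.011, and adjusted p = 0.38 with an estimated correlation). The list as written also holds H1f0, a linker histone that is not replication-dependent and was among those that rose (0.46). Cytosolic ribosomal protein genes fell in 47 of 48 and rose in 0 (median -0.72, adjusted p = 2.7e-14, and adjusted p = 0.094 with an estimated correlation). Their share of all counts was 1.425% ± 0.0293 in control and 1.001% ± 0.00595 with LINC01133 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). The difference was -0.424 percentage points, or -0.711 with the 10 most abundant rows left out of the total. Rpl30, not called by TMM (0.11), was called higher by library size alone (0.35) and by upper quartile (0.21). The share of the histone list was 0.121% ± 0.00501 and 0.0975% ± 0.00047 by the same exact test (p = 0.1), a difference of -0.023 percentage points, or -0.043 without those rows in the total. Nuclear OXPHOS genes fell in 23 of 30 and rose in 1 (median -0.58, or -0.34 by library size alone, adjusted p = 6.7e-06, and adjusted p = 0.13 with an estimated correlation), among them Cox4i1 (-1.40), while Cox5b, not called by TMM (0.05), was called higher by library size alone (0.30) and by upper quartile (0.15).

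Hypoxia and glycolysis genes fell in 21 of 31 members and rose in 9 (median -0.43, or -0.18 by library size alone, mean 0.03, adjusted p = 0.03, and adjusted p = 0.27 with an estimated correlation, and adjusted p = 0.054 with the CPM filter, range 0.0028 to 0.054). The phosphofructokinase gene Pfkl fell from 426.2 ± 9.30 to 106.2 ± 0.585 CPM and Pfkfb3 rose from 2.96 ± 0.315 to 58.8 ± 1.42 CPM. Targets of p53 fell in 13 of 20 and rose in 4 (median -0.39, or -0.15 by library size alone, adjusted p = 0.048, and adjusted p = 0.19 with an estimated correlation), a call lost under 5 of 14 settings, among them without LINC01133 replicate 1 (adjusted p = 0.055; range 0.013 to 0.077). Cdkn1a, the cyclin-dependent kinase inhibitor p21, fell from 70.7 ± 1.79 to 24.8 ± 1.31 CPM and Perp rose from 0.237 ± 0.0658 to 31.6 ± 0.940 CPM. Nuclear noncoding RNAs were not called (5 higher and 1 lower of 9, adjusted p = 0.074; median 0.60, or 1.26 without a count filter, mean -0.07); Malat1 rose from 486.6 ± 13.7 to 1792 ± 19.4 CPM.

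**Figure D3:**
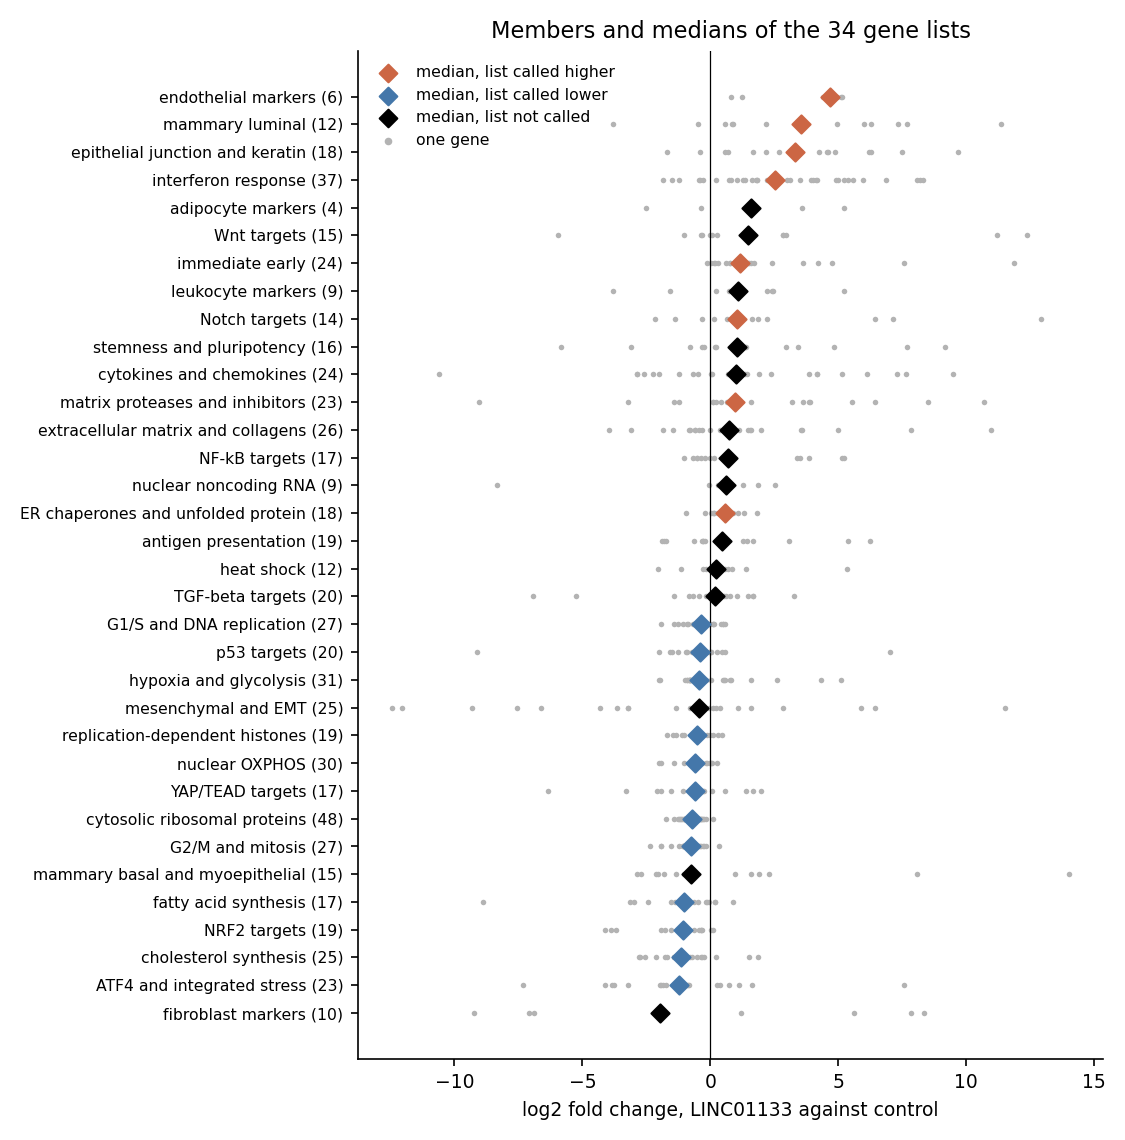
Log2 fold changes of LINC01133 against control for the tested members of 34 gene lists, with the number of members in brackets; grey points are genes and diamonds are list medians, coloured by the call of camera at the preset correlation. The 8 lists called higher and 12 called lower overlap widely in their members' values, and none was called with an estimated correlation.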

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

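Leaving out the Rn45s row and following the 2-fold counts through the settings were chosen after seeing the data. The counts of called genes stayed within 1.5 times the main counts under each change of scaling, filter, dispersion or tool. The same held without any 1 library (6228 to 6379 higher and 5632 to 5669 lower). No main call was called in the opposite direction except by library size alone (299 genes) and upper quartile (4 genes). Genes that changed sign and lost their call, such as Calr by library size alone, are not in these numbers. A 2-fold limit left 2860 higher and 1959 lower genes, by its construction. Without a count filter 4543 genes were 2-fold higher, against 2860, as 22697 genes were then tested. Fits with the replicate block gave 6188 higher and 5629 lower genes; samples of the same number did not deviate together (r = -0.11, -0.10 and -0.02 across 5334 genes), so the numbers are not taken to pair the samples. Of lists, 0 were higher and 0 lower with an estimated correlation, 17 were higher with fry, which asks another question, and 5 were higher by library size alone; the cause of the last was not tested. With the 10 most abundant rows out of the denominator, the shares of ribosomal protein and histone counts differed by -0.711 and -0.043 percentage points, against -0.424 and -0.023, since those rows took 30.54% of control counts and 25.33% of LINC01133 counts. Signs reversed by library size alone for Calr (0.04), Ier2 (0.10), cytokines (direction of the test; median 1.26) and adipocyte markers (likewise; 1.84). With fry the direction of the test reversed for cytokines (median 1.02), heat shock (0.23), basal (-0.77) and adipocyte markers (1.60), and with the filter of 1 CPM for basal markers (-0.81); the cause was not tested. Gstm1, not called, lay between -0.06 and 0.11 without any 1 library. Over all named genes and settings, 7 other values passed the threshold that had not by TMM, all by library size alone or upper quartile. With its direction kept, 1 lost its call (Ier2, upper quartile), and 2609 kept both direction and side. Calr, whose sign reversed by library size alone, lost its call there too. In a single library 3 counts correspond to 0.0827 to 0.128 CPM, so levels at or below these rest on few counts.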

Other observations

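The X-linked and chromosome-wide values, the admixture counts, the genes with no read in one group and the scaling of ribosomal genes were tested only after the result was seen; the length, window and split tests were set before. The window test was first run with a minimum of 5 CPM and with shorter windows at chromosome ends, neither of which had been written down; that first version would have left both copy-number readings below open. The version as written decides, and the results of all 4 versions are given.

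Genes lost with LINC01133 were concentrated on the X chromosome. Of 135 genes with at least 5 CPM in the controls and under 1% of it with LINC01133, 24 were X-linked (17.8%, against 3.1% of the 8987 genes at that level; Fisher's exact test, odds ratio 7.38, 95% interval 4.45 to 11.79). Of the 160 genes gained by the same limits, 3 were X-linked. Outside the naming rule and chosen after their values were seen, Nxf3 fell from 8272 to 4 counts and Zfp275 from 7318 to 6 counts over the 3 libraries of each group. Chromosome medians differed too: among genes with a mean of at least 5 CPM, 358 of 449 on chromosome 3 (median log2 fold change -0.80), 379 of 471 on chromosome 17 (-0.59) and 195 of 276 on the X chromosome (-0.37) were lower, while 186 of 608 on chromosome 5 were (0.30). On chromosome 3, windows of 50 neighbouring genes at all levels had medians of 0.23 and 0.41 from 5218526 to 52353221, against -1.02 to -0.63 in the others. Among all 246 windows, the lowest median, picked after the values were seen, was that from 6399854 to 20699880 on the X chromosome (-1.09, with 45 genes lower), while the other X-linked windows had medians of -0.37 to -0.12.

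For the at least 2-fold differences, the tables argue against a gene length trend, since 98.2% of these genes kept a 2-fold difference once the trend was removed. They also argue against added cells in one group alone as the whole difference. In the controls, 80 genes at 20 CPM or more lay under 1% of that with LINC01133, and 76 the other way round, where admixture would leave the diluted transcripts. Added cells as a part of the difference were not tested. The values are consistent with unequal chromosome copy number as part of the difference: window medians had an SD of 0.353, against at most 0.169 in 1000 shuffles of gene order (with short windows, 0.362 against 0.743; from 5 CPM, 0.335 against 0.141, and 0.364 against 0.526 with short windows). As the whole difference it is argued against by the 84.5% of 2-fold genes left after window medians were removed, past the bound of 80% set before, although from 5 CPM 74.1% were left, 72.8% with short windows and, at all levels with short windows, 84.4%. Cells of another origin or clone in one group cannot be told apart from an effect of LINC01133 by the genes with no read. At 20 CPM or more in one group, 19 genes had no read in the other, which either could give. The labels do not say whether both groups came from the same parental cells, and no parental sample was analysed here. The step between windows on chromosome 3 and the lower medians of chromosomes 3 and 17 would go with groups whose cells differ in copy number. Whether such a difference arose before or after the vector was introduced was not tested. An effect of LINC01133 beside it stays open. The real split gave 11990 calls by edgeR and the highest of the other splits 0 (at most 5 genes at an unadjusted p under 0.05). Each other split mixes both groups, so the large difference between groups enters their spread and few calls were possible. The splits therefore cannot decide whether the grouping arose by chance, and 1 of 10 splits is too few for a share under 0.05.

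For the loss of Xist and of X-linked transcripts, a loss alike on all chromosomes is argued against by the 17.8%, above the 95% range of 0.7% to 5.9% in 10000 random draws. A lower dosage of the whole X chromosome is argued against as the cause of the near-complete losses, since it would lower X-linked genes alike. Under 1% of their control level were 24 X-linked genes, while 239 stayed at 5 CPM or more in both groups. As a smaller shift of those remaining genes it stays open. Their median, which leaves out the lost genes, lay 0.26 below that of autosomal genes. The difference (-0.26, 95% bootstrap interval -0.33 to -0.15) lay between the bounds set. Loss of an inactive X chromosome could remove Xist with no change in dosage, and this test does not address it. An effect of LINC01133 on these genes is likewise open and untested.

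For the lower ribosomal protein transcripts, a gene length trend is argued against by the median of -0.63 with the trend removed, and the choice of scaling by a median of -0.48 under the scaling that raised it most. Growth rate or cell origin may differ between the groups and were not tested, and an effect of LINC01133 stays open beside them.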
